A study of Mus musculus with 9 samples.

How the data were processed

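RNA from the cerebral cortex of 9 mice (sham_WT, IR_WT and IR_Matn3_ko, 3 each) was sequenced as poly(A)-selected, strand-marked libraries with molecular identifiers, as paired reads on a NovaSeq instrument, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. The deposited table lists 37893 genes with mouse Ensembl identifiers, a FPKM column and a raw count column per library, per the file headers. The raw counts were deposited by the authors as whole numbers that were not normalized, and the FPKM values were deposited as fragments per kilobase of gene relative to all mapped fragments. All per-sample columns were used, and no entry lacked a gene. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR were named, with no role or order. Whether the deposited counts are of molecules or of reads, and whether they use the strand, is not given in the sources used here, so genes that overlap another on either strand are uncertain. The notes name the build GRCh38, which is human. Of the identifiers 37764 are in the mouse annotation GENCODE M21 (GRCm38), 34742 of them (92%) at identical coordinates, so coordinates are printed as the table gives them, as GRCm38. For 78 symbols more than 1 gene shares the name, and the gene with the highest mean count stood for the symbol in the gene lists.

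Genes with at least 0.5 FPKM in at least 3 of the 9 libraries were tested (17247). The design fixed before the data were examined had limma on log2(FPKM + 1) as the main test and foresaw edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) should the table hold counts. As it does, edgeR 4.0.16 on the deposited counts was used, with TMM scaling (factors 0.948 to 1.07), the 9 libraries in 1 model with a mean per group (6 residual degrees of freedom), both comparisons as contrasts, and Benjamini-Hochberg adjustment at a threshold of 0.05. Fold changes are given with a standard error computed from the test, and CPM values are scaled by the TMM factors, except those of Matn3 and of the markers of other tissues, which are relative to the total counts. Total counts of 53400376 to 68370527 per library set the precision. Each library counted as a sample because the labels give separate mice. Replicates differed from each other by more than sampling noise (chi-square per degree of freedom between 23.8 and 80.9 within groups). Those differences show that no library repeats another, but not that the mice are separate. A fold against a group with no counts was computed against a floor of 3 counts per library. The single gene Matn3 was compared with two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.

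Gene lists (53, of markers of brain cell types, inflammation, matrix, stress, other brain regions, blood and RNA quality) were fixed before the data were examined and tested with limma 3.58.1 camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list moves on balance in 1 direction. For each list the members past the threshold were counted after adjustment over all genes and adjusted over the list alone. The genes named were Matn3, the 6 with the largest fold change in each direction among genes past the threshold with no overlap between the groups, at least 1 FPKM in 1 group and a name that is not a clone or predicted name, and up to 4 members of each list past the threshold with the largest change, or the 2 with the highest FPKM where none passed. Where fewer than 12 genes passed, those with the smallest p filled the 12. Not all lists are described in the text, and the others enter only the numbers of lists called. Genes named outside this rule were chosen after their values were seen.

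Markers of tissues other than brain were examined after such transcripts were noticed, with 10 lists written after the data were seen. Libraries with over 10 summed CPM of the small intestine list formed the second of 2 library sets, and a term for the set (5 residual degrees of freedom left) was added to the model. The covariance of the 2 comparisons was set against 100 simulated data sets in which the groups were unchanged. KEGG terms from the table's own annotation were tested with a one-sided hypergeometric test among tested genes with a term.

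The procedures were tested on simulated data made from the real means, library sizes and dispersions, with 17247 genes. For IR_WT against sham_WT edgeR recovered 76 of 100 genes changed 2-fold and 94 of 100 changed 4-fold with 6 false calls, and for IR_Matn3_ko against IR_WT 57 and 92 with 9 false calls. DESeq2 1.42.0 recovered 85 and 96 with 46 false calls in the first, and 70 and 96 with 54 in the second. Camera called the 1 list raised 1.5-fold and 1 of the other lists. Genes were simulated independently of each other, so this does not test false list calls from correlated genes. With the real libraries of a comparison split into other groups of 3, camera called 9 to 28 lists in the first comparison and 10 to 29 in the second.

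Alternatives fixed before the data were examined were limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.5, with and without a trend, and in its robust form; no filter and a filter at 1 FPKM; TPM, quantile-normalized values and median-ratio size factors; only the 6 libraries of a comparison; the replicate number as a block; DESeq2; a 2-fold minimum; and leaving out each library. Added after seeing the data were the library set term, the omission of genes called for it, edgeR's robust form and no scaling factors. R 4.3.3 was used.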

Results

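Messenger RNA was sequenced from the cerebral cortex of 9 mice in 3 groups of 3. Wild-type mice had sham surgery (sham_WT). Other wild-type mice (IR_WT) and mice lacking Matn3 (IR_Matn3_ko) had the middle cerebral artery blocked for 60 min, followed by 1 day of reperfusion. Matn3 encodes matrilin-3, a matrix protein best known from cartilage. The design text names 2 comparisons, IR_WT against sham_WT and IR_Matn3_ko against IR_WT, and asks how matrilin-3 limits glial scar formation. No sham-operated knockout group was analysed here, so an effect of the genotype without ischemia could not be separated from its effect after ischemia. The labels give separate mice, 3 per group. Total counts per library lay between 53400376 and 68370527, and 17247 genes were expressed highly enough to test. At these depths a count of 0 allowed up to 0.0439 to 0.0562 CPM (counts relative to the library total), a limit that covers counting error only.

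The libraries fell into 2 sets that followed the groups in large part. All sham_WT libraries lay in the first set, all IR_Matn3_ko libraries in the second, and only IR_WT was divided. Transcripts of the small intestine, such as Sis, Reg3b and Fabp2, summed to 0.668 to 1.58 CPM in the 3 sham_WT libraries and IR_WT replicate 1. In IR_WT replicates 2 and 3 and the 3 IR_Matn3_ko libraries they summed to 132 to 544 CPM, with all 15 markers apart. B cell and lymphoid transcripts ran the other way, at 218 to 320 CPM against 10.1 to 25.2 CPM, with 12 of 12 markers apart. Keratinocyte transcripts summed to 65.3 to 173 CPM in the first set and 4.74 to 5.75 CPM in the second, with 7 of 10 markers apart. Cartilage transcripts divided the libraries differently: they summed to 251 to 273 CPM in sham_WT replicates 2 and 3 and IR_WT replicate 1, but to 33.2 CPM in sham_WT replicate 1 and 19.0 to 25.2 CPM in the second set, with 1 of 10 markers apart between the sets. These 2 library sets, of 4 and 5 libraries, are used below as a term of the model: the difference between IR_WT and sham_WT then comes from IR_WT replicate 1 alone, and that between IR_Matn3_ko and IR_WT from IR_WT replicates 2 and 3. The effect of the library set itself comes from IR_WT replicate 1 against IR_WT replicates 2 and 3, so any trait of that 1 mouse is part of it. The first principal component, the axis of largest variance in log2 CPM (60.7%), also separated the sets. It stood at -70.8 to -68 in sham_WT, -35.5 in IR_WT replicate 1, and 40.3 to 55.9 in the second set.

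**Figure D1:**
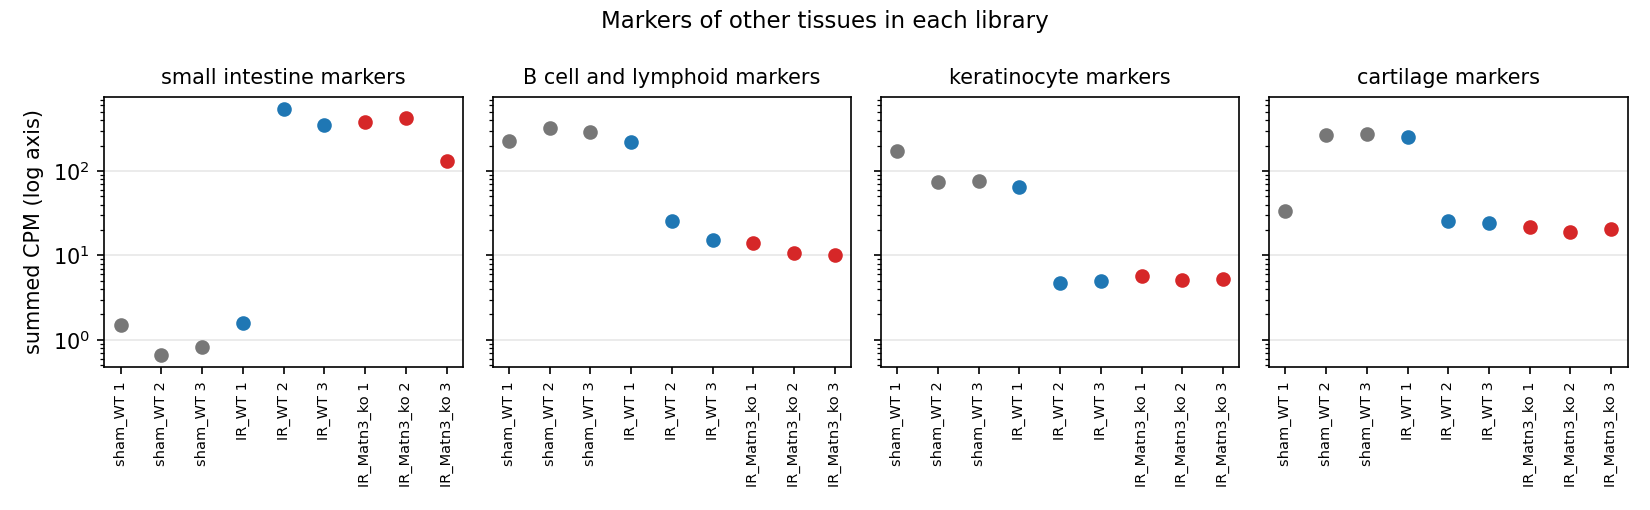
Summed CPM of marker genes of small intestine, B cells and lymphoid tissue, keratinocytes and cartilage in each of the 9 libraries, on a log axis, with 1 point per library and colours for the groups. Small intestine transcripts lie at 0.668 to 1.58 CPM in the 3 sham_WT libraries and IR_WT 1 and at 132 to 544 CPM in the other 5, and lymphoid transcripts at 218 to 320 CPM and 10.1 to 25.2 CPM.

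Matn3 (chromosome 12, 8947929 to 8972028, GRCm38) was low in every library, at 0 to 48 counts. Its counts were 0, 4 and 26 in sham_WT replicates 1 to 3, 33, 12 and 48 in IR_WT, and 0, 17 and 0 in IR_Matn3_ko. The mean was 0.0513 ± 0.0734 FPKM (SD, n = 3) in sham_WT, 0.15 ± 0.0879 FPKM in IR_WT and 0.0249 ± 0.0431 FPKM in IR_Matn3_ko. Neither difference from IR_WT passed a two-sided exact permutation test (p = 0.2 for both, where 0.1 is the smallest p that 3 against 3 libraries allow). The gene failed the expression filter, and without it edgeR gave adjusted p = 0.7 for IR_WT against sham_WT and 0.679 for IR_Matn3_ko against IR_WT. A sham_WT library also stood at 0, and the 17 counts of IR_Matn3_ko replicate 2 lay within the range of IR_WT, so Matn3 cannot check the labels. That library is therefore named below as the library labelled IR_Matn3_ko 2. Without it, 0 of the 34 genes named in the knockout comparison changed direction.

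After ischemia and reperfusion, wild-type cortex carried far more mRNA of reactive astrocytes, of activated microglia and macrophages, and of secreted inflammatory factors. Of 15 myelin genes 7 fell and of 21 synaptic genes 4 fell, but neither list held (adjusted p = 0.245 and 0.0699 with an estimated correlation). Gfap, the intermediate filament of reactive astrocytes (chromosome 11, 102887336 to 102897200), rose from 51.7 ± 17.2 to 538 ± 69.6 CPM (SD, n = 3 per group), a log2 fold change of 3.38 ± 0.28 (SE; edgeR adjusted p = 0.000326). The macrophage scavenger receptor Msr1 (chromosome 8, 39581685 to 39642673) rose by a log2 fold change of 5.94 ± 0.32 (adjusted p = 3.13e-05) and the chemokine Ccl2 (chromosome 11, 82035571 to 82037453) by 6.81 ± 0.47 (adjusted p = 0.000118). P2ry12, the purine receptor of resting microglia (chromosome 3, 59216272 to 59262871), fell from 50.7 ± 4 to 18.9 ± 3.30 CPM, a log2 fold change of -1.42 ± 0.16 (adjusted p = 0.00139). These 4 genes passed whichever single library was left out.

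In all, 701 genes passed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 438 higher and 263 lower in IR_WT, and 331 of them differed at least 2-fold. DESeq2 called 1664 genes (962 higher and 702 lower), and the library set term left 407 (293 and 114), of which 305 were among the 701. The count was 242 without sham_WT replicate 1, 315 without sham_WT replicate 2, 366 without sham_WT replicate 3 and 398 without IR_WT replicate 2. The share of higher calls depended on the scaling: it was 62.5% here, 79.2% with no scaling factors (591 higher and 155 lower), 82.3% by limma on TPM (424 and 91) and 75.7% by limma on FPKM (445 and 143), but 62.4% with median-ratio factors and 55.1% by limma on quantile-normalized values (282 and 230). TPM also shifted the median of all genes by 0.10 on the log2 scale. The 3 libraries of 1 group lay above the 3 of the other for 4412 genes (25.6%, where chance gives 10%).

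Among astrocyte genes, 8 of 13 measured pan-reactive markers rose (11 adjusted over the list alone) and none fell, with a median log2 fold change of 2.02 over the list and 2.15 with the library set term. The acute-phase lipocalin Lcn2 rose by 4.18 ± 0.60 (SE; adjusted p = 0.00537), the protease inhibitor Serpina3n by 3.88 ± 0.27 (adjusted p = 0.000118) and the small heat shock protein Hspb1 by 2.86 ± 0.49 (adjusted p = 0.0125). Of the A2-type markers 7 of 12 rose (8 adjusted over the list alone), among them Tgm1 at 4.36, Cd14 at 3.25 and Ptgs2 at 1.45. Of the A1-type markers 3 of 13 rose (7 adjusted over the list alone). Camera called all 3 lists higher. The pan-reactive call held with an adjusted p = 0.00654 with an estimated correlation, and the other calls were lost, with adjusted p = 0.0735 with an estimated correlation for A2 and adjusted p = 0.203 for A1. No member of the homeostatic astrocyte list passed (camera adjusted p = 0.275). Hspb1 missed the threshold without sham_WT replicate 1 (adjusted p = 0.0736).

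Of 20 measured markers of activated microglia and macrophages, 17 rose (18 adjusted over the list alone), with a median log2 fold change of 2.06 and 1.94 with the library set term. Besides Msr1 these included osteopontin, Spp1, at 4.55 ± 0.35 (SE; adjusted p = 0.000185), the chemokine Ccl4 at 4.27 ± 0.75 (adjusted p = 0.0141) and cystatin F, Cst7, at 4.16 ± 0.63 (adjusted p = 0.00692). The list held with an adjusted p = 0.000209 with an estimated correlation. Of 12 homeostatic microglia markers 4 rose and 1, P2ry12, fell (4 and 3 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.216). Fcrls, one of the 4, rose by 1.86 ± 0.22 (adjusted p = 0.00167). Ccl4 missed the threshold without sham_WT replicate 1 or 2, where its adjusted p reached 0.0587.

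Of 20 cytokines and chemokines 11 rose (14 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 2.25 and 2.14 with the library set term. Ccl2 and Ccl12 (5.12 ± 0.36, SE; adjusted p = 0.000118) and Il11 (4.65 ± 0.83, adjusted p = 0.0148) were among them. Il6 had no count in the 3 sham_WT libraries and a mean of 1.88 ± 2.00 CPM in IR_WT (SD, n = 3), at least 32.8-fold above the floor of 3 counts per library. Most of that came from IR_WT replicate 1, with 4.18 CPM against 0.829 and 0.620 CPM in replicates 2 and 3, and without it the bound was at least 12.7-fold. Of 14 complement genes 10 rose (12 adjusted over the list alone), with a median of 1.13. The anaphylatoxin receptors C5ar1 and C3ar1 rose by 4.12 ± 0.36 (adjusted p = 0.000394) and 2.81 ± 0.16 (adjusted p = 4.12e-05), C4b by 3.51 ± 0.39 (adjusted p = 0.00116) and C1qb by 1.23 ± 0.12 (adjusted p = 0.00076). C4b has a near-identical copy, so its value is uncertain. Both lists held, with adjusted p = 0.00147 with an estimated correlation for the cytokines and adjusted p = 0.00143 with an estimated correlation for complement. Il6 missed the threshold without any 1 of the sham_WT replicates (adjusted p up to 0.0686) and Il11 without sham_WT replicate 3 (adjusted p = 0.0697). The size for Il11 is uncertain too, at a log2 fold change of 4.06 to 6.49 when 1 library was left out.

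Members of stress lists rose too, and of these lists that of metallothionein and antioxidant genes alone held with an estimated correlation. Of 18 metallothionein and antioxidant genes 6 rose (11 adjusted over the list alone), led by heme oxygenase, Hmox1, which went from 6 ± 1.22 to 48.8 ± 8.30 CPM (log2 fold change 3.02 ± 0.22, SE; adjusted p = 0.000154), with Slc7a11 at 1.07, Txnrd1 at 0.91 and Srxn1 at 0.86. The list held with an adjusted p = 0.0144 with an estimated correlation. Of 14 heat shock genes 4 rose (9 adjusted over the list alone), among them Hspa1b at 4.52 and Hspa1a at 4.30, near-identical copies whose separate values are uncertain, and Bag3 at 1.28. That list's camera call was lost, with adjusted p = 0.245 with an estimated correlation. Of 14 JAK-STAT3 targets 7 rose (8 adjusted over the list alone), including Osmr at 2.73, Cebpd at 2.63, Socs3 at 2.54 and Lif at 2.18 (adjusted p = 0.0692 with an estimated correlation). Of 17 p53 and apoptosis genes 4 rose (8 adjusted over the list alone), including Cdkn1a at 1.68 and Fas at 1.40 (adjusted p = 0.13 with an estimated correlation). Of 16 unfolded protein response genes 15 lay higher (median 0.33), with 0 higher and 1 lower past the threshold (2 and 1 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00164), a call lost with adjusted p = 0.447 with an estimated correlation. With single libraries left out, Hspa1b (adjusted p up to 0.056), Slc7a11 (0.0503), Cdkn1a (0.0732) and Lif (0.124) missed the threshold. Each did so without sham_WT replicate 1, Cdkn1a also without sham_WT replicate 2 or IR_WT replicate 2, and Lif also without sham_WT replicate 2 or 3 or IR_Matn3_ko replicate 3.

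Matrix genes moved unevenly. Of 18 matrix proteases and inhibitors 7 rose (10 adjusted over the list alone), with the stromelysin Mmp3 at a log2 fold change of 7.35 ± 0.92 (SE; adjusted p = 0.00231), Mmp12 at 5.95 ± 0.85 (adjusted p = 0.00509) and Adamts9 at 3.22 (adjusted p = 0.0658 with an estimated correlation for the list). Of 20 genes of chondroitin sulfate proteoglycans and the glial scar, none rose and 1 fell (0 and 3 adjusted over the list alone), the sulfotransferase Chst3 at -1.40 ± 0.34 (adjusted p = 0.0494), and the list did not pass (camera adjusted p = 0.126). Of 17 fibrillar collagen and fibrotic scar genes Postn rose by 1.88 ± 0.24 (adjusted p = 0.00288) and Col5a1 fell by 1.16 on the log2 scale (adjusted p = 0.00112). Adjusted over the list alone 2 and 2 passed, and the list did not pass (camera adjusted p = 0.682). Its median was -0.32, but 0.37 with the library set term, where IR_WT is replicate 1 alone, and -0.73 without IR_WT replicate 1. Relative to the sham_WT mean, the list stood at 0.83, -0.47 and -0.48 in IR_WT replicates 1 to 3. The sham_WT replicates stood at -1.08, 0.55 and 0.51. Whether fibrotic scar genes moved as a list thus cannot be told from these libraries. Both endothelial selectins, Selp and Sele, rose, by 5.24 ± 0.58 (adjusted p = 0.00119) and 3.04 ± 0.42 (adjusted p = 0.00419), among 3 of 11 activated endothelial genes (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.0735 with an estimated correlation). The fold changes of Mmp3 and Mmp12 rest on counts in 1 sham_WT library each: without sham_WT replicate 3 and sham_WT replicate 1 respectively no sham_WT count was left, so the sizes are uncertain, although both genes passed whichever library was left out. Chst3 missed the threshold without any 1 of 7 libraries (adjusted p up to 0.155).

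Some genes of myelin and of synapses fell. Of 15 myelinating oligodendrocyte genes 7 fell (9 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.70 and -0.63 with the library set term. Among them were Mog (log2 fold change -0.94, adjusted p = 0.00445), Aspa (-0.998, adjusted p = 0.0489) and Opalin (-0.93, adjusted p = 0.0353). The list's camera call was lost, with adjusted p = 0.245 with an estimated correlation. Of 21 synaptic vesicle and receptor genes 4 fell (7 adjusted over the list alone) and none rose, among them syntaxin-1A, Stx1a, from 344 ± 22.2 to 205 ± 16.8 CPM (log2 fold change -0.75 ± 0.09, SE; adjusted p = 0.00206), Rims1 at -0.65 and Shank3 at -0.46. For this list the call was lost too, with adjusted p = 0.0699 with an estimated correlation. Its median was -0.24, and -0.32 with the library set term, where IR_WT is replicate 1 alone. Lists of another brain region, of neurons and of mitochondrial transcripts lay lower beside them and were lost: striatal genes (10 of 11 lower, median -0.62; adjusted p = 0.18 with an estimated correlation), pan-neuronal genes (11 of 15 lower, -0.15; adjusted p = 0.493) and mitochondrially encoded genes (all 13 lower, -0.15, and 0.06 with the library set term; adjusted p = 0.737). Aspa, Opalin and Shank3 missed the threshold in 8, 5 and 6 of the 9 fits that left out 1 library, with adjusted p up to 0.142, 0.138 and 0.103.

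The largest increases included transcripts that followed the library sets. Lyz1, Muc3, Ifi27l2b and H2-Q2 had no count in sham_WT and were at least 516-fold, 108-fold, 67.3-fold and 56.3-fold above the floor of 3 counts per library in IR_WT, but IR_WT replicate 1 held only 0.224, 0.189, 0.0860 and 0.275 CPM of them, against 38.9 and 49.5 CPM of Lyz1 in the other IR_WT libraries. Without the highest IR_WT library the bounds were 342-fold, 72.7-fold, 35.4-fold and 33.3-fold. Sis had a log2 fold change of 7.82 (adjusted p = 0.0254) and 2.07 with the library set term (adjusted p = 0.38). With that term H2-Q2 still passed (adjusted p = 0.014), while Lyz1, Muc3 and Ifi27l2b did not (adjusted p = 0.226, 0.261 and 0.205). The stress cytokine Gdf15 (chromosome 8, 70629393 to 70632456) was also at 0 in sham_WT and at least 43.6-fold higher in IR_WT, with 2.39, 3.44 and 1.65 CPM in replicates 1 to 3, and it passed whichever library was left out. Lowest were the microRNA precursor Mir212 at -1.91, Col24a1 at -1.87, Cbln4 at -1.67, the T cell receptor constant gene Trac at -1.48, cortistatin, Cort, at -1.46, and P2ry12. The lymphocyte list had a median of -1.48 (camera adjusted p = 0.00729, and adjusted p = 0.29 with an estimated correlation), -0.29 with the library set term and -4.69 without IR_WT replicate 1. Lyz1 and Lyz2, and the H2-Q and Ifi27l2 genes, have close copies, so their separate values are uncertain. Of the 9 fits that left out 1 library, Lyz1, Muc3, Ifi27l2b, H2-Q2, Sis, Mir212, Col24a1, Cbln4, Trac and Cort passed in only 2, 1, 2, 6, 5, 0, 2, 7, 3 and 4, with adjusted p up to 0.138, 0.134, 0.127, 0.0639, 0.109, 0.156, 0.167, 0.0659, 0.127 and 0.109.

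**Figure D2:**
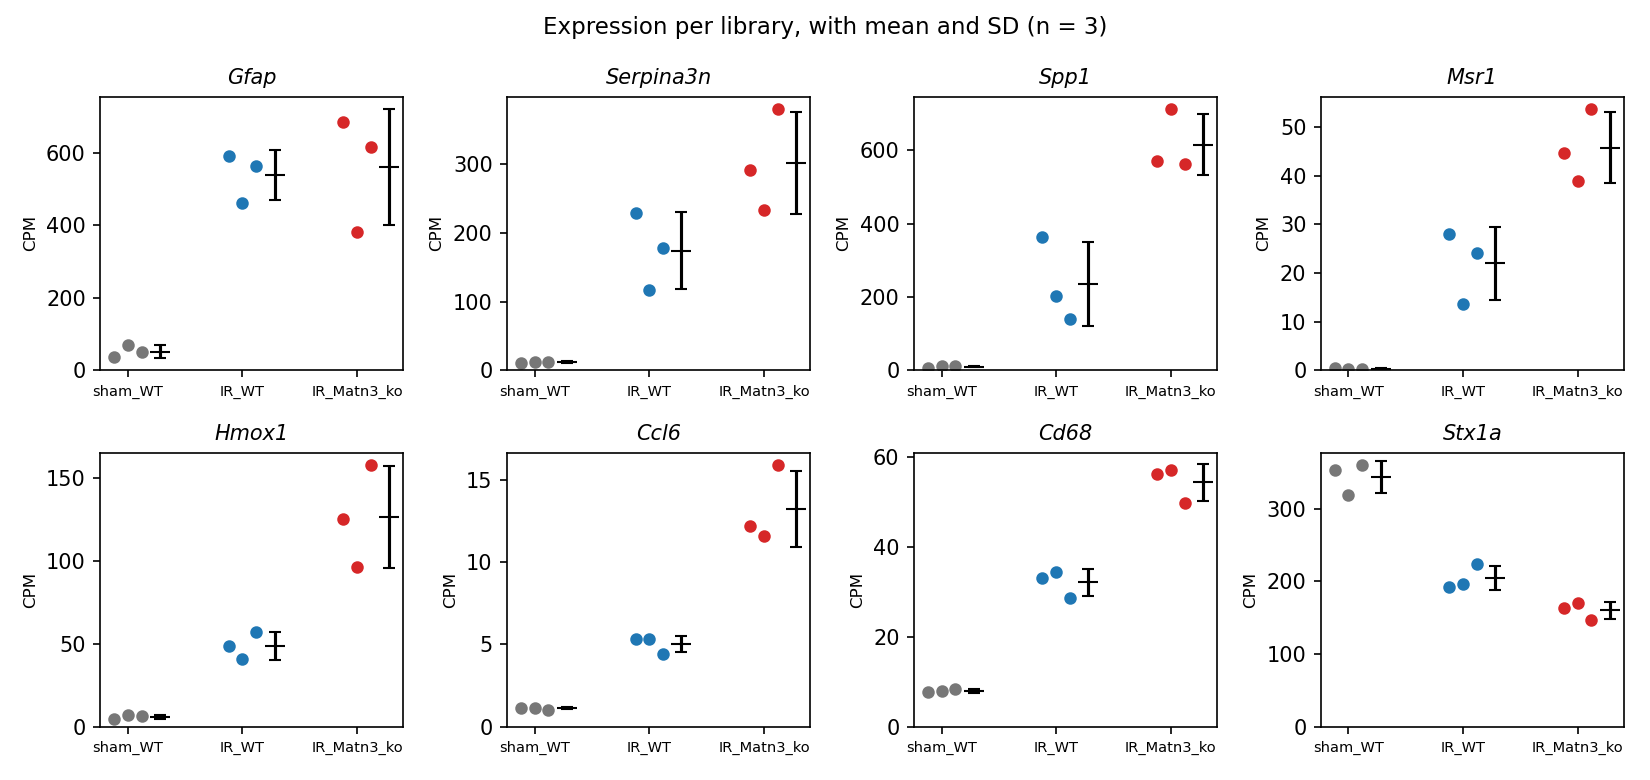
CPM of 8 genes in each library of the 3 groups, with 1 point per library and a black bar for the mean with its SD (n = 3). Gfap has a mean of 51.7 CPM in sham_WT, 538 CPM in IR_WT and 560 CPM in IR_Matn3_ko, Cd68 stands at 32.0 CPM in IR_WT and 54.3 CPM in IR_Matn3_ko, and Stx1a falls from 344 CPM in sham_WT to 205 CPM in IR_WT.

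In the knockout cortex after ischemia, 5 lists lay higher than in ischemic wild-type cortex, also with an estimated correlation. They were activated microglia, cytokines, complement, metallothionein and antioxidant genes, and A2-type astrocytes. The list of synaptic genes lay lower, also with an estimated correlation. With the library set term as well, the calls for complement and for metallothionein and antioxidant genes were lost. No single gene passed correction over all genes in edgeR. Among the 12 genes with the smallest p, the chemokine Ccl6 (chromosome 11, 83587882 to 83593087) stood at 5.02 ± 0.51 CPM in IR_WT and 13.3 ± 2.34 CPM in IR_Matn3_ko (SD, n = 3), the lysosomal protein Cd68 (chromosome 11, 69664213 to 69666153) at 32.0 ± 3.00 and 54.3 ± 4.04 CPM, and the lipid droplet protein Plin2 (chromosome 4, 86648386 to 86670060) at 24.1 ± 6.79 and 59.1 ± 2.14 CPM. Each of the 3 was higher in all 3 IR_Matn3_ko libraries than in any IR_WT library, at an adjusted p of 0.0752. Gfap stood at 538 ± 69.6 and 560 ± 160 CPM, a log2 fold change of 0.06 ± 0.26 (SE; adjusted p = 0.952), whose sign turned without IR_WT replicate 2 (-0.04), without IR_Matn3_ko replicate 1 (-0.11) and without IR_Matn3_ko replicate 3 (-0.01).

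Of 17247 genes, edgeR called 0 at an adjusted p under 0.05, with 2302 at an unadjusted p under 0.05. DESeq2 called 668 (373 higher and 295 lower) and limma on log2(FPKM + 1) called 38 (35 and 3). With the library set term edgeR called 34 (29 higher and 5 lower). It called 37 without IR_WT replicate 1 and 61 without the library labelled IR_Matn3_ko 2, and 0 without any other 1 library. The 3 libraries of 1 group lay above the 3 of the other for 3079 genes (17.9%, where chance gives 10%).

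The 12 genes with the smallest p all had an adjusted p of 0.0752. Besides Ccl6, Cd68 and Plin2, the ferritin light chain Ftl1 had a log2 fold change of 0.75 ± 0.10 (SE), heme oxygenase, Hmox1, 1.37 ± 0.20 (48.8 ± 8.30 CPM in IR_WT and 126 ± 30.7 CPM in IR_Matn3_ko; SD, n = 3), Hmga1 0.68 ± 0.10, the Fc receptor gamma chain Fcer1g 0.85 ± 0.13, Tm4sf1 1.36 ± 0.20 and the lysosomal tetraspanin Cd63 0.61 ± 0.09. Lower in the knockout libraries were Nwd1 at -0.77 ± 0.09 (chromosome 8, 72646711 to 72717876; 63.8 ± 4.50 and 37.4 ± 3.16 CPM), the synaptic organizer Cbln2 at -0.94 ± 0.14 and protein kinase C alpha, Prkca, at -0.60 ± 0.09. Ftl1 has close copies in the genome and its value is uncertain. Named after their values were seen, Spp1 (log2 fold change 1.85 ± 0.22), Emp1 (1.63 ± 0.20), C3ar1 (1.11 ± 0.14) and the oligodendrocyte precursor receptor Gpr17 (-1.36 ± 0.15) were among the 34 genes past the threshold with the library set term, as were Nwd1, Ccl6, Cd68, Plin2, Ftl1, Hmga1, Cbln2, Tm4sf1 and Cd63. Without that term Spp1 had 1.39 ± 0.30 and an adjusted p of 0.123, Emp1 1.16 and 0.152, C3ar1 0.95 and 0.0752, and Gpr17 -1.02 and 0.221. With the term, IR_WT replicate 1 does not enter this difference. That library had 14.01 CPM of Gpr17, within the knockout range of 13.56 to 17.54 CPM. IR_WT replicates 2 and 3 had 41.63 and 34.59 CPM, so the call for Gpr17 depends on setting replicate 1 aside. For Spp1, Emp1 and C3ar1, IR_WT replicate 1 lay below every IR_Matn3_ko library, at 362.6, 24.85 and 28.75 CPM.

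No list member passed over all genes. Of 20 activated microglia and macrophage genes 12 were higher and 1 lower adjusted over the list alone, with a median log2 difference of 0.80 and 0.77 with the library set term. The 2 with the highest expression went apart: Apoe stood at 671 ± 163 CPM in IR_WT and 436 ± 134 CPM in IR_Matn3_ko (SD, n = 3; adjusted p = 0.278) and the lysosomal protease Ctsd at 456 ± 78.9 and 569 ± 71.8 CPM (adjusted p = 0.352). Of 20 cytokines and chemokines 12 were higher adjusted over the list alone, with a median of 1.17 and 1.42 with the term. Il33, an alarmin, had a log2 fold change of 1.11 ± 0.28 (SE, edgeR adjusted p = 0.149) and Ccl12 0.86 ± 0.28 (adjusted p = 0.227). When 1 library was left out, Il33 ranged from 0.746 to 1.4 and Ccl12 from 0.429 to 1.065. Of 14 complement genes 6 were higher adjusted over the list alone (median 0.41), C1qa at 0.41 (adjusted p = 0.335) and C1qb at 0.39 (adjusted p = 0.214). Of 18 metallothionein and antioxidant genes 10 were higher adjusted over the list alone (median 0.34), with Mt2 at 1.26 (adjusted p = 0.116) and Mt1 at 0.69 (adjusted p = 0.152). Camera called these 4 lists higher, with adjusted p = 0.00286 with an estimated correlation for activated microglia and adjusted p = 0.0077 with an estimated correlation for the cytokines. It gave adjusted p = 0.029 with an estimated correlation for complement and adjusted p = 0.0208 with an estimated correlation for metallothionein and antioxidant genes. With the library set term as well the calls for complement and for metallothionein and antioxidant genes were lost (adjusted p = 0.0581 for both).

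Lists of other phagocytes were called higher by camera too, but were lost: 10 genes of infiltrating monocytes and neutrophils had a median of 0.67 and 1.19 with the library set term (3 higher adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), and 6 of border-associated macrophages 0.90 (3 higher and 1 lower; adjusted p = 0.119 with an estimated correlation). Relative to sham_WT, the monocyte and neutrophil list stood at 1.38 and 1.05 in IR_Matn3_ko replicates 1 and 3 but at -0.17 in the library labelled IR_Matn3_ko 2.

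Of the astrocyte lists, only the A2-type list held with an estimated correlation. Of 12 A2-type genes 9 were higher adjusted over the list alone, with a median log2 difference of 1.11 and 1.49 with the library set term. Cd14 had 1.78 ± 0.44 (SE, edgeR adjusted p = 0.148) and S100a10 0.49 ± 0.14 (adjusted p = 0.192). The Cd14 value ranged from 1.03 to 2.17 when 1 library was left out. Cd14 stood at 67.7 and 150 CPM in IR_Matn3_ko replicates 1 and 3, 31.2 CPM in the library labelled IR_Matn3_ko 2, and 21.5 to 28.2 CPM in IR_WT. The A2 list held with an adjusted p = 0.0487 with an estimated correlation. Of 13 pan-reactive genes 6 were higher adjusted over the list alone, with a median of 0.79, and Serpina3n stood at 175 ± 56.3 and 302 ± 73.8 CPM (SD, n = 3; adjusted p = 0.202). That list was called by camera and lost, with adjusted p = 0.0818 with an estimated correlation. Of 14 homeostatic astrocyte genes 5 were lower adjusted over the list alone, with a median of -0.52, glutamine synthetase, Glul, at -0.47 and Aldoc at -0.48 (adjusted p = 0.31 and 0.436), and the call was lost with adjusted p = 0.208 with an estimated correlation. The median was -0.30 without the library labelled IR_Matn3_ko 2, which stood at -1.32 relative to sham_WT against -0.43 and -0.53 for replicates 1 and 3.

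Of 20 genes of chondroitin sulfate proteoglycans and the glial scar 5 were lower adjusted over the list alone and none higher, with a median log2 difference of -0.18. The perineuronal proteoglycan Bcan stood at 126 ± 22.9 CPM in IR_WT and 75.7 ± 10.2 CPM in IR_Matn3_ko (SD, n = 3; adjusted p = 0.116) and the link protein Hapln4 at 152 ± 19.1 and 92.4 ± 20.5 CPM (adjusted p = 0.126). Camera called the list lower, a call lost with adjusted p = 0.121 with an estimated correlation. The 17 fibrillar collagen and fibrotic scar genes did not pass as a list (camera adjusted p = 0.104; median 0.02), with 1 higher adjusted over the list alone. With the library set term 15 of the 17 were higher (median 0.47; camera adjusted p = 0.000382), a call lost with adjusted p = 0.359 with an estimated correlation. All 21 synaptic vesicle and receptor genes were lower, 12 of them adjusted over the list alone, with a median of -0.32 and -0.34 with the library set term, and the list held with an adjusted p = 0.0253 with an estimated correlation. Other neuronal lists lay lower with it and were lost: pan-neuronal genes (14 of 15 lower, median -0.22; adjusted p = 0.229 with an estimated correlation), cortical excitatory neurons (-0.18; adjusted p = 0.0896) and voltage-gated ion channels (-0.27; adjusted p = 0.0818). All 13 mitochondrially encoded genes were lower as well (median -0.22, and -0.10 with the library set term; adjusted p = 0.54 with an estimated correlation). All 30 ribosomal protein genes were higher, 25 adjusted over the list alone (median 0.30), a camera call lost with adjusted p = 0.119 with an estimated correlation. The lymphocyte list had a median of -3.24 and the matrilin and cartilage matrix list -0.82, and these were -0.17 and 0.02 with the library set term (adjusted p = 0.222 and 0.367 with an estimated correlation). In that last list Col2a1 stood at 65.1 ± 109 and 3.68 ± 0.97 CPM, and its log2 fold change turned from -4.14 to 0.59 with the term, and Sox9 had -0.13.

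**Figure D3:**
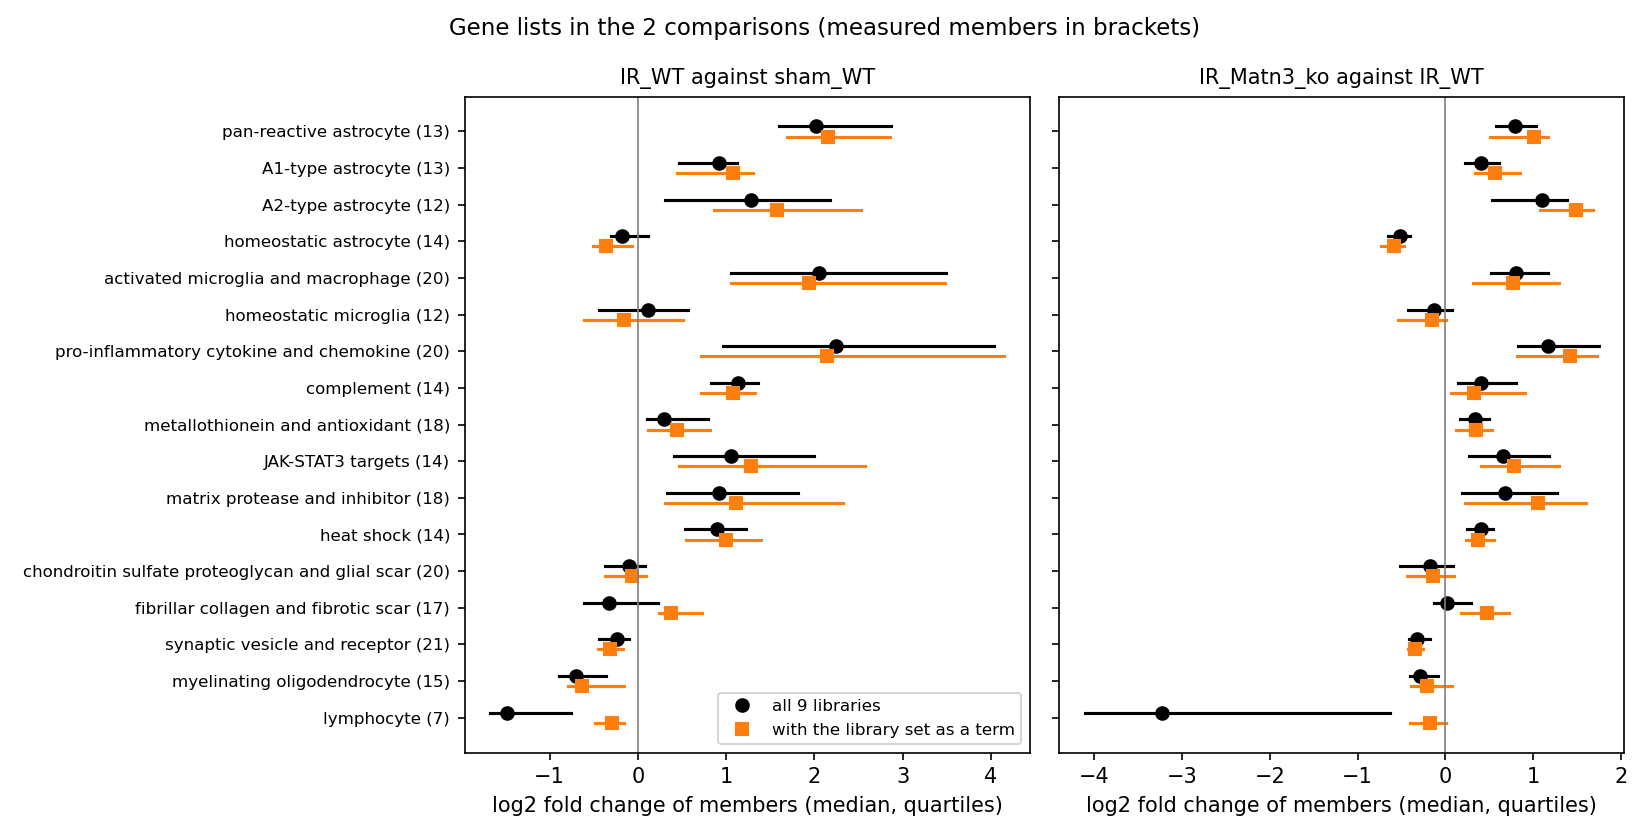
Median log2 fold change of the members of 17 gene lists, with bars for the quartiles of the members, from all 9 libraries (black circles) and with the library set as a term (orange squares), for both comparisons. Activated microglia and macrophage genes have a median of 2.06 in IR_WT against sham_WT and 0.80 in IR_Matn3_ko against IR_WT, and lymphocyte genes move from -3.24 to -0.17 in the second comparison once the library set is a term.

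A block of neighbouring genes was lowest in IR_Matn3_ko replicates 1 and 3, with the library labelled IR_Matn3_ko 2 between these and the wild-type libraries. Of the 61 genes edgeR called without that library (26 higher and 35 lower), 22 lay between 41809083 and 42613253 on chromosome 4 (GRCm38), among 36 tested there, and 0 lay on the chromosome of Matn3. The log2 fold changes of the 22 ranged from -6.64 to -1.37. The 22 genes summed to 27.5 and 25.4 CPM in replicates 1 and 3, 123 CPM in the library labelled IR_Matn3_ko 2, 167 to 202 CPM in IR_WT and 211 to 271 CPM in sham_WT. Many are copies of each other, so their separate values are uncertain.

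**Figure D4:**
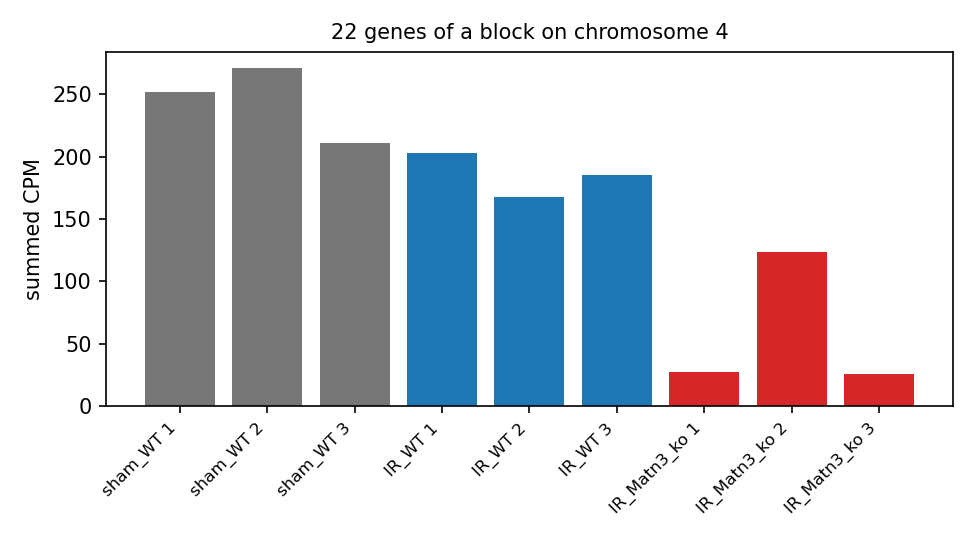
Summed CPM of the 22 genes of the chromosome 4 block in each of the 9 libraries, with 1 bar per library. The sums are 27.5 and 25.4 CPM in IR_Matn3_ko replicates 1 and 3, 123 CPM in the library labelled IR_Matn3_ko 2, and 167 to 271 CPM in the other 6.

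In total, 28 of the 53 lists were called by camera in IR_WT against sham_WT (17 higher and 11 lower) and 33 in IR_Matn3_ko against IR_WT (21 and 12). With an estimated correlation 5 and 6 of them held: pan-reactive astrocyte, activated microglia, cytokine, complement and metallothionein in the first comparison, and A2-type astrocyte, activated microglia, cytokine, complement, metallothionein and synaptic genes in the second. With the library set term and an estimated correlation 11 and 4 held. In the first comparison these added A2-type astrocyte (adjusted p = 0.0258), matrix protease (0.0258), JAK-STAT3 (0.0283), activated endothelial (0.0258), border-associated macrophage (0.0371) and synaptic genes (0.0371) to the 5, and in the second complement and metallothionein were lost.

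Across genes, the log2 fold changes of the 2 comparisons had a covariance of 0.126 and a correlation of 0.443, where genes are not independent replicates. Both comparisons use the IR_WT libraries with opposite signs, which alone gave a covariance of -0.0538 (range -0.0610 to -0.0486 over 100 simulated data sets of unchanged groups) and a correlation of -0.495, and the observed covariance exceeded that by 0.180. The simulated data held no library sets, which follow the groups in part, so the excess does not tell a shared response from the sets. The 3 IR_WT libraries cannot be split into parts of at least 2. The covariance was 0.0901 with a correlation of 0.377 between IR_WT replicate 1 minus sham_WT and IR_Matn3_ko minus IR_WT replicates 2 and 3, which share no library and lie within the library sets. Without IR_WT replicate 1 the covariance turned to -0.0215, against -0.0809 simulated for that case (range -0.0917 to -0.0722), a difference of 0.0594. That simulation used dispersions from all 9 libraries, which include the spread between IR_WT replicate 1 and the other IR_WT libraries. Its value may thus be too low, and no conclusion is drawn from the difference. No gene was called in both comparisons by edgeR, which called none in the second. With the library set term 28 genes were called in both, 26 higher in both (0.493 expected from independent lists) and 2 lower in both (0.033 expected), and 0 in opposite directions. Both lists come from that 1 fit and share its dispersions, so they are not independent and the expected counts may be too low. In that fit the first comparison has a single IR_WT library. Of the 29 genes higher in the knockout 17 were also called higher in IR_WT without the term.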

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

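The library set term, the omission of its genes, edgeR's robust form, no scaling factors and the comparison within the library sets were chosen after seeing the data. For IR_WT against sham_WT, the 701 genes became 418 with no filter, 331 with a 2-fold minimum, 1664 with DESeq2, 407 with the library set term, and 242 to 996 when 1 library was left out. The other settings gave 512 to 753, apart from the replicate block below. For IR_Matn3_ko against IR_WT, the 0 genes became 38, 15 and 27 by limma with pseudocounts of 1, 0.1 and 0.5, 25 on TPM, 30 on quantile-normalized values, 44 without a trend, 84 in the robust form, 668 with DESeq2, 34 with the library set term, and 0 to 61 when 1 library was left out. The 28 lists of the first comparison became 5 with an estimated correlation, 17 with fry, 11 with the library set term and an estimated correlation, and 25 to 31 when 1 library was left out; the 33 of the second became 6, 14, 4 and 31 to 36. No list called in both the original and another setting changed direction. The relation of the 2 contrasts, a covariance of 0.126, became 0.0303 on log2(FPKM + 1), 0.0293 on quantile-normalized values, and -0.0215 to 0.135 when 1 library was left out, the lowest and only negative value without IR_WT replicate 1. The difference in Matn3 between IR_Matn3_ko and IR_WT stayed between -0.173 and -0.087 FPKM. The causes were not tested, except that a 2-fold minimum leaves fewer calls by construction.

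The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.151 and 0.116, over 0.1 in 1 of 9 pairs. With the replicate block 410 and 0 genes and 29 and 33 lists were called, in the order of the comparisons. Of the 78 genes named in the first comparison, 38 passed in all 26 alternatives, 45 passed whichever library was left out, and 0 changed direction. Of the 34 named in the second, 2 changed direction: Gfap (0.06, and up to 0.27 without IR_Matn3_ko replicate 2) without IR_WT replicate 2 (-0.04), IR_Matn3_ko replicate 1 (-0.11) or IR_Matn3_ko replicate 3 (-0.01), and Col2a1 (-4.14, and down to -4.72 without IR_WT replicate 2) without IR_WT replicate 1 (0.60) or with the library set term (0.59). Depth limits Matn3, at up to 48 counts.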

Other observations

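The KEGG test, the library sets and the tests of the 3 patterns below were chosen after the data had been seen, and only the counts over other splits of the libraries were planned. For the correlation within the library sets the limits were written before it was computed. Among the genes higher in IR_WT than in sham_WT, 17 of the 39 tested genes annotated to complement and coagulation cascades were called (1.74 expected; adjusted p = 4.2e-11), and 30 of 148 annotated to cytokine-receptor interaction (6.61 expected; adjusted p = 1.68e-10). A lysosome group also stood out, with 13 of 113 genes called (5.05 expected; adjusted p = 0.0164), among them the cathepsins Ctsb, Ctsc, Ctsd, Ctsl and Ctsz with Cd68. The ferroptosis term had 8 of 38 (1.70 expected; adjusted p = 0.0034), including the cystine transporter subunits Slc7a11 and Slc3a2, the zinc and iron carrier Slc39a14 and heme oxygenase, Hmox1. Among lower genes the MAPK term led with 16 of 258 (4.72 expected; adjusted p = 0.00444), and its members included the calcium channel subunits Cacna1e, Cacna1i, Cacna2d1, Cacna2d3, Cacnb3 and Cacnb4. With the library set term the first 2 terms stayed (12 of 39, adjusted p = 1.56e-07, and 29 of 148, adjusted p = 1.22e-13), the lysosome and ferroptosis terms did not pass, no term passed among lower genes, and the MAPK term passed among higher genes instead (18 of 258, 8.01 expected; adjusted p = 0.00927). Terms share members, so they are not independent. With 1 library left out Ctsb, Ctsd, Slc3a2, Slc39a14, Cacna1e, Cacna1i, Cacna2d1 and Cacnb4 passed in only 1, 5, 6, 6, 3, 2, 2 and 3 of the 9 fits, with adjusted p up to 0.159, 0.128, 0.0747, 0.0732, 0.114, 0.137, 0.155 and 0.142.

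Neither immediate early genes nor hypoxia genes moved as lists in IR_WT against sham_WT, 1 day after reperfusion. In IR_Matn3_ko against IR_WT camera called the immediate early list (median log2 difference 0.32), a call lost with an estimated correlation. Of 24 immediate early genes 2 were higher and 1 lower over all genes in IR_WT (3 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.866): Atf3 rose by a log2 fold change of 3.59 ± 0.28 (SE; adjusted p = 0.000202) and Fosl1 by 2.07 ± 0.42 (adjusted p = 0.0267), while Egr1 fell by 1.26 on the log2 scale (adjusted p = 0.035). With 1 library left out Fosl1 and Egr1 missed the threshold in 2 and 5 of the 9 fits (adjusted p up to 0.118 and 0.112), and Egr1 had -0.78 without sham_WT replicate 2. Of 17 hypoxia and glycolysis genes 0 were higher and 2 lower by edgeR (2 and 2 adjusted over the list alone; camera adjusted p = 0.891), and 1 of the lower ones was Vegfa (-0.76 ± 0.12, adjusted p = 0.00931). The list of infiltrating monocytes and neutrophils did not pass in IR_WT against sham_WT (camera adjusted p = 0.733), while camera called it higher in IR_Matn3_ko against IR_WT (adjusted p = 0.00204, and adjusted p = 0.164 with an estimated correlation).

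The first pattern is that transcripts of other tissues split the libraries into 2 sets. Ischemia itself is argued against, though by 1 library, since IR_WT replicate 1 had 0.012 of the small intestine CPM of the lowest of the other 5 ischemic libraries. A milder injury in that mouse was not seen in its astrocyte, microglia and cytokine genes. They lay 0.21 above those of the other IR_WT libraries (median log2 difference, with a 95% bootstrap interval over 50 genes of -0.014 to 0.39). That interval covers the spread between genes and not between mice, so it cannot decide on the injury of 1 mouse. RNA or reads of other tissues in both sets may be the source: 25 of 42 lymphoid, keratinocyte, cartilage and heart markers (59.5%) were fully apart between the sets, against 6 of 36 markers of 5 control tissues (16.7%) and 1809 of all 17247 tested genes (10.5%). The limit set for that test, also after the data were seen, was 60%, so the test stays undecided. It pooled the cartilage markers, which divided the libraries differently, and left out the small intestine markers, which defined the sets. That transcripts of other tissues differ between the sets is shown by the sums given above. When or how RNA of other tissues would have entered was not tested.

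The second pattern is the higher level of microglial and inflammatory genes in IR_Matn3_ko. The library set as a whole cause is argued against, because the median of the activated microglia list kept 0.965 of its value with the set as a term. The genetic background shared by IR_Matn3_ko replicates 1 and 3, described next, stays open, because only 1 knockout library lies outside it and its label is in doubt. In the activated microglia list that library, labelled IR_Matn3_ko 2, lay 0.93 above IR_WT replicates 2 and 3 (0.73 and 0.77 for the other knockout libraries), but in the monocyte and neutrophil list it stood at -0.17 relative to sham_WT, against 1.38 and 1.05 for the other knockout libraries and 0.16 to 0.39 for IR_WT. A larger or further advanced ischemic response in the knockout samples may account for it: across genes, the knockout difference followed the ischemia difference with a correlation of 0.38 where the comparisons share no library and lie within the library sets. A larger infarct by chance, a sampling site nearer to it, or an effect of Matn3 could each give this, and 3 mice per group with no sham knockout do not separate them. Not every list followed the ischemia difference. Cholesterol synthesis genes had a median of -0.191 in IR_WT against sham_WT and 0.305 in IR_Matn3_ko against IR_WT, and ribosomal protein genes 0.048 and 0.301. Neither list held with an estimated correlation. The 6 lists that did in the knockout comparison had medians of the same sign in both comparisons.

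The third pattern is a block on chromosome 4 (41809083 to 42613253, GRCm38) with lower expression in IR_Matn3_ko replicates 1 and 3. Its 22 genes, which include Ccl21b, Gm13301 and Gm10599 and are near-identical copies of each other in part, summed to 27.5 and 25.4 CPM there, 123 CPM in the library labelled IR_Matn3_ko 2, and 167 to 271 CPM in the 6 wild-type libraries. An action of the Matn3 deletion on its neighbours is argued against, with 0% of these calls within 20 Mb of Matn3 and 0 of the 61 genes called without that library on its chromosome. A strain variant carried by those mice may be the source and stays open: 36.1% of the 61 calls lay in this 1 window, which holds 36 tested genes, and that share restates the pattern. Outside it, Gm15446 on chromosome 5 stood at 2.33 and 2.09 CPM in IR_Matn3_ko replicates 1 and 3. It had 30.5 CPM in the library labelled IR_Matn3_ko 2 and 31.6 to 46.2 CPM in the wild-type libraries. In the same order Gm16867 on chromosome 14 stood at 1.06, 1.24, 13.9 and 19.7 to 41.8 CPM. The mitochondrial mt-Tg stood at 0.353, 0.283, 4.67 and 3.43 to 8.91 CPM. The library labelled IR_Matn3_ko 2 thus lay at or near the wild-type levels of Gm15446 and mt-Tg, and below those of Gm16867. A list of genes that differ between substrains, fixed before the data were examined, was called lower in IR_Matn3_ko against IR_WT by camera (8 of 12 lower; adjusted p = 0.0222), a call lost with adjusted p = 0.121 with an estimated correlation. Whether the library labelled IR_Matn3_ko 2 carries a wrong label cannot be told apart from a mixed background, because Matn3 had as few as 12 counts in an IR_WT library.

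Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. The real split of IR_WT and sham_WT gave 701 genes, with 3 the highest of the others, so 1 split reached it. For IR_Matn3_ko and IR_WT it gave 0 genes, with 2 the highest of the others, so all 10 splits reached it. For gene lists the real splits gave 28 and 33, with 28 and 29 the highest of the others, reached by 2 and 1 splits. DESeq2 gave 1664 and 668 genes for the real splits, with 184 and 246 the highest of the others.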
